A study of Mus musculus with 8 samples.

How the data were processed

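RNA was measured in 8 libraries of PyMT-1099 mouse breast cancer cells, 2 for each of 4 groups: parental cells and Agps knockout cells, untreated and given TGF-β at 2 ng/ml for 10 days. Per the labels' protocols, cells grew in high glucose DMEM with serum, RNA was taken up on RNeasy columns, and libraries of polyadenylated RNA were made with the KAPA mRNA HyperPrep kit.

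Per the submitters' processing notes, reads were aligned with STAR 2.7.1a to the mouse genome (GRCm38, also named mm10) and counted per gene with featureCounts 1.6.2. The deposited count files, 1 per library, hold whole raw counts for 55450 gene identifiers, and no step after counting was found in them. The annotation release, the strandedness of counting and any filter are not given in the sources used here. The authors also deposited a table of normalized values (unit: signal), and per the submitters' processing notes DESeq2 1.26.0 was used. Each of its columns equalled the raw counts divided by a single number per library to within 0.45%, and that number matched a DESeq2 size factor computed from the counts. It holds no sample beyond the 8 libraries, so the counts alone were analysed.

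Of the 55450 identifiers 30946 had a count in any library. Genes were kept with edgeR's filterByExpr (minimum count 10, by group), which left 14641 genes holding 99.9% of the counts. Library totals ran from 17007268 to 21311831 counts and were scaled by TMM. A single edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) with 1 mean per group over all 8 libraries left 4 residual degrees of freedom. It gave 5 contrasts: TGF-β in parental cells, TGF-β in knockout cells, knockout against parental cells without and with TGF-β, and the difference of the TGF-β changes between the lines. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 are called changed. Log2 fold changes are those of the fit, with standard errors derived from the fit's F statistic, and levels are CPM after TMM as mean and SD of 2 libraries. In each of the 168 named gene results between a pair of groups, the libraries of the groups did not overlap. This was required of the largest rises and falls, and list members were chosen by adjusted p, so it adds no separate support. A gene with 0 counts in a group of libraries is compatible with up to 3 counts, and such floors cover counting error only. Levels or counts and no fold are given for genes with 3 or fewer counts in a group.

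The samples carry replicate numbers, but with 2 per group and no statement of what a number shares, they were not used as a block in the fit reported. The comparisons, their gene and list tests, the rule for named genes, 24 gene lists and all but 1 of the alternatives were fixed before the data were examined, while most tests of explanations were chosen after the results were seen. The rule names Agps, the 6 largest rises and falls of each contrast among genes of an average log2 CPM of at least 3, and up to 4 called members of each list of an average log2 CPM of at least 1. Between a pair of groups, a largest rise or fall also needed both libraries of 1 group above both of the other. It also names a set of key genes of epithelial state, iron and ether lipids. Some genes that the rule selects are not reported here. The lists hold 540 genes, of which 428 were tested. They cover the TGF-β response, transcription factors of epithelial to mesenchymal transition, mesenchymal markers, contractile genes, epithelial markers, collagens and matrix, ether lipid synthesis, the peroxisome, cholesterol synthesis, fatty acid synthesis and desaturation, ferroptosis and iron handling. They also cover NRF2 targets, unfolded protein and amino acid stress, the cell cycle, the interferon response, cytokines and chemokines, glycolysis and hypoxia, basal, luminal, immune, endothelial and adipocyte markers, and mitochondrially encoded genes.

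Lists of more than 2 tested genes were tested against all other genes with camera (limma 3.58.1, voom values, preset correlation 0.01), adjusted over 115 tests of 23 lists in 5 contrasts. Of these 49 passed with the preset correlation and 0 with a correlation estimated from the residuals, where 17 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0971. With an estimated correlation camera also rests on the 4 residual degrees of freedom, so a lost call does not show that correlated genes caused it. For mesenchymal markers with TGF-β in parental cells the estimate was -0.0261, below the preset. The unadjusted camera p still went from 5.15e-12 to 0.00169. The fry test, which asks whether genes of a list move one way without comparing them with other genes, passed 50, and 32 passed both it and camera. Counts of called members adjusted over the list alone are given in the report where they differ from those over all genes.

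Gene positions, overlap between annotated exons and shared 50-base sequences were taken from the GENCODE M21 annotation and the GRCm38 genome. The alternatives were RLE and upper quartile scaling, no count filter and a minimum count of 50, DESeq2 1.42.0, limma-voom, a replicate block, a fit on only the libraries compared, a fold minimum and each library left out. A fit without the genes of 5 chromosome segments was added after the data were seen. The method was checked on simulated counts with 50 changed genes at each of several fold sizes among 14114 genes. A 2-fold change was recovered in 66% of genes for TGF-β in parental cells and in 52% for the difference between lines, and a 4-fold change in 88% and 78%, while 14 and 8 unchanged genes were called. Recovered genes numbered 20, 33, 44 and 48 at 1.5, 2, 4 and 8-fold for TGF-β, and 11, 26, 39 and 45 for the difference. In the data 6228 genes were called with TGF-β in parental cells, so calls and scaling at that share were not tested. No read files were used, and sequence variants and exon usage of Agps were not analysed here.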

Results

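Polyadenylated RNA was sequenced from PyMT-1099 cells, a line derived from a mammary tumour of a mouse carrying the polyoma middle T oncogene and used as a model of epithelial to mesenchymal transition. The 8 libraries form 4 groups of 2: parental cells and Agps knockout cells, each without treatment and after TGF-β at 2 ng/ml for 10 days. Agps encodes alkylglycerone phosphate synthase, a peroxisomal enzyme of ether lipid synthesis. Library totals were 18945324 and 17007268 counts in untreated parental cells and 19282972 and 17103804 counts in parental cells with TGF-β. They were 20396165 and 21311831 counts in untreated knockout cells and 20066517 and 17790157 counts in knockout cells with TGF-β. Principal components were computed on only the genes that varied most between the libraries. Of the variance of those genes, the first component held 82.2% and parted treated from untreated libraries, and the second held 11.9% and parted the lines. The libraries of a group correlated at 0.991 to 0.994 across genes (Pearson's r), and genes are not independent replicates. Mitochondrially encoded genes took 2.36% to 4.31% of the counts of a library. Of 13 listed, 7 passed the count filter, and mt-Co2, mt-Co3 and mt-Atp6 did not, so this share need not be that of all mitochondrial RNA. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

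The knockout was first looked for in the counts of its target. Agps (ENSMUSG00000042410, GRCm38 chromosome 2, 75832177 to 75931350) stood at 343.5 ± 19.4 CPM (the count scaled to the library total; SD, n = 2) in untreated parental cells and at 31.1 ± 2.52 CPM in untreated knockout cells. The log2 fold change of -3.47 (standard error 0.12) had an adjusted p of 5.44e-08 in the edgeR quasi-likelihood test. With TGF-β the levels were 265.5 ± 0.98 CPM in parental and 39.8 ± 5.87 CPM in knockout cells, a log2 fold change of -2.74 (standard error 0.11, adjusted p = 2.62e-07). Agps transcripts were thus reduced in all 4 knockout libraries and still present in each.

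**Figure D1:**
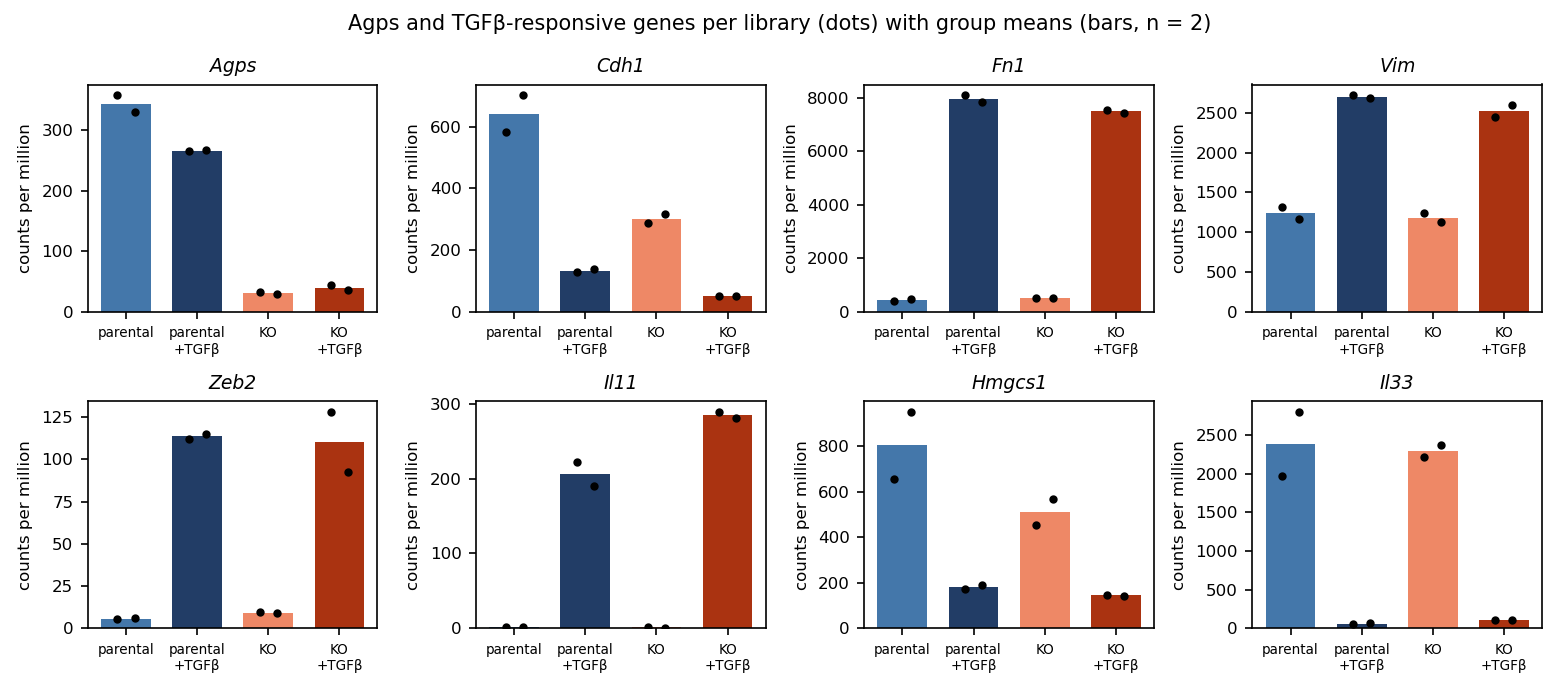
Levels (CPM) of Agps and of 7 genes that changed with TGF-β, with dots for libraries and bars for the mean of each group (n = 2), in 4 groups by line and treatment. Agps falls from 343.5 to 31.1 CPM between untreated parental and knockout cells, while Fn1 rises to 7962 CPM in parental and 7493 CPM in knockout cells with TGF-β.

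The first comparison asked how parental cells respond to TGF-β. With camera's preset correlation the lists of mesenchymal, matrix and contractile genes rose and those of sterol and fatty acid synthesis and NRF2 targets fell, and none passed with an estimated correlation. Fn1, which encodes fibronectin (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), went from 424.5 ± 54.4 to 7962 ± 186 CPM (SD, n = 2), a log2 fold change of 4.23 (standard error 0.12, adjusted p = 7.98e-10 in edgeR). Cdh1, which encodes E-cadherin (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), dropped from 641.9 ± 84.4 to 133.8 ± 8.65 CPM, a log2 fold change of -2.26 (standard error 0.11, adjusted p = 2.39e-08). The intermediate filament gene Vim rose by 1.12 on the log2 scale, from 1241 to 2703 CPM. In all, 6228 of 14641 genes passed at an adjusted p under 0.05, with 3119 higher and 3109 lower (3448 and 2829 with upper quartile scaling), and 2688 of them changed by at least 1 on the log2 scale.

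Genes that TGF-β is known to induce moved upward in parental cells. Of 24 measured genes of the TGF-β response list, 16 rose and 3 fell, and 4 fell when adjusted over the list alone (camera adjusted p = 3.35e-06; adjusted p = 0.315 with an estimated correlation). The cytokine gene Il11 rose from 1.36 to 205.7 CPM (log2 fold change 7.24), and Ltbp1, which encodes a binding protein of latent TGF-β, rose by 5.21 on the log2 scale. Inhba, an activin subunit gene, rose by 3.96. Transcription factors of the transition rose in 9 of 10 cases and fell in 0 (camera adjusted p = 1.73e-06; adjusted p = 0.294 with an estimated correlation). Among them Zeb2 went from 5.66 ± 0.618 to 113.6 ± 2.02 CPM, and Hmga2, Runx1 and Zeb1 rose by 2.57, 1.62 and 1.41 on the log2 scale.

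Mesenchymal markers rose in 17 of 19 cases with 1 lower (camera adjusted p = 2.96e-10; adjusted p = 0.0971 with an estimated correlation). Pdgfrb, a growth factor receptor gene, climbed from 0.281 to 84.5 CPM, a log2 fold change of 8.22 (standard error 0.19). Of 25 collagen and matrix genes, 21 rose and 3 fell (camera adjusted p = 5.75e-09; adjusted p = 0.168 with an estimated correlation). Col7a1, which encodes the collagen of anchoring fibrils, rose by 6.87 on the log2 scale. Contractile genes rose in 11 of 12 cases with 1 lower (camera adjusted p = 9.96e-08; adjusted p = 0.234 with an estimated correlation). Acta2, which encodes smooth muscle actin, rose by 6.75 on the log2 scale, from 0.688 to 75.2 CPM, and Cnn1, which encodes calponin, by 3.07. Cd44, which encodes a hyaluronan receptor, rose by 1.49.

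Epithelial markers went both ways. Of 22 measured, 14 fell and 7 rose (camera adjusted p = 0.0195, toward lower; adjusted p = 0.468 with an estimated correlation). The tight junction genes Ocln and Marveld2 fell by 3.77 and 3.59 on the log2 scale. Cldn4, another tight junction gene, moved the other way and held 16 counts in the untreated and 526 counts in the treated parental libraries, and its log2 fold change of 5.04 was 6.89 or 4.30 without replicate 1 or 2 of the untreated parental cells. Basal and myoepithelial markers rose in 3 and fell in 4 of 7 cases (camera adjusted p = 0.657 and fry adjusted p = 0.0173, both toward lower), with the keratin gene Krt5 at a log2 fold change of -3.64 and the integrin gene Itgb4 at -1.07. Of 5 luminal markers 2 fell, Muc1 by 3.02 and the transcription factor gene Ehf by 2.78 on the log2 scale, and 1 more rose when adjusted over the list alone (camera adjusted p = 0.226 and fry adjusted p = 0.0026, both toward lower).

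Lipid synthesis genes were lower with TGF-β in parental cells. Cholesterol synthesis genes fell in 23 of 25 cases and rose in 0 (camera adjusted p = 1.08e-09; adjusted p = 0.458 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate and has 12.1% of its exonic length under a gene on the opposite strand, dropped from 804.6 ± 208 to 182.2 ± 12.5 CPM. Insig1, a regulator of sterol synthesis, fell by 1.78 on the log2 scale and Sqle, which encodes squalene epoxidase, by 1.51. Fatty acid genes fell in 17 of 22 cases with 1 higher (camera adjusted p = 1.56e-06; adjusted p = 0.468 with an estimated correlation), Acss2, an acetyl-CoA synthetase gene, by 2.12. Ether lipid genes, the pathway of Agps, fell in 10 of 15 cases and rose in 0, or 12 and 1 adjusted over the list alone (camera adjusted p = 9.36e-04; adjusted p = 0.268 with an estimated correlation). Of these, Chpt1, a choline phosphotransferase gene, fell by 1.75 and Pcyt2, of ethanolamine lipid synthesis, by 0.99. Peroxisome genes fell in 15 and rose in 2 of 31 cases, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.00142; adjusted p = 0.468 with an estimated correlation), with the catalase gene Cat at -1.66, Pxmp4 at -1.50 and Ech1 at -1.40.

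NRF2 targets and ferroptosis genes fell in parental cells as well. NRF2 targets fell in 14 of 18 cases, 15 adjusted over the list alone, and rose in 0 (camera adjusted p = 3.37e-07; adjusted p = 0.468 with an estimated correlation). The glutathione transferase gene Gsta4 fell by 4.46 on the log2 scale and the epoxide hydrolase gene Ephx1 by 2.35. Ferroptosis genes fell in 11 and rose in 2 of 23 cases (camera adjusted p = 0.0086; adjusted p = 0.506 with an estimated correlation). Gss, of glutathione synthesis, which shares 15.4% of its exonic length with genes on the opposite strand, fell by 1.92, and Acsl4, which activates polyunsaturated fatty acids, by 1.83. Iron handling genes fell in 12 and rose in 4 of 23 cases (camera adjusted p = 0.109 and fry adjusted p = 0.0236, both toward lower). The siderophore-binding gene Lcn2 fell by 2.82 and the metalloreductase gene Steap4 rose by 1.59, while the ferritin heavy chain gene Fth1 fell by 0.74.

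Cell cycle genes fell in 19 of 32 cases and rose in 0 (camera adjusted p = 1.17e-04; adjusted p = 0.390 with an estimated correlation), by less than 1 on the log2 scale in the examples Aurkb (-0.87), Ccnb2 (-0.81) and Kif11 (-0.76), all of mitosis. Interferon response genes fell in 16 and rose in 2 of 28 cases (camera adjusted p = 0.00471; adjusted p = 0.294 with an estimated correlation). Of 17 cytokine and chemokine genes, 8 fell and 5 rose (camera adjusted p = 0.311 and fry adjusted p = 0.0164, both toward lower). Il33, an alarmin gene, dropped from 2386 ± 585 to 61.3 ± 15.6 CPM (log2 fold change -5.28), and the chemokine gene Ccl20 fell by 2.92. Glycolysis and hypoxia genes fell in 13 and rose in 4 of 27 cases (camera adjusted p = 0.0649). The hypoxia-induced genes Egln3 and Pdk1 fell by 2.59 and 1.82 and Pfkfb4, a regulator of glycolysis, rose by 1.84. Stress genes of the unfolded protein and amino acid responses fell in 12 and rose in 6 of 26 cases (camera adjusted p = 0.168), with the transcription factor gene Atf3 at -2.40. Mitochondrially encoded genes rose in 3 of 7 cases, 5 adjusted over the list alone, and fell in 0 (camera adjusted p = 0.0748).

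Several genes known from other cell types rose with TGF-β in parental cells. Among 5 measured immune markers 4 rose and 1 fell (camera adjusted p = 0.0851), and among 4 endothelial markers 2 rose and 0 fell (camera adjusted p = 0.0645). Cdh5, which encodes VE-cadherin, went from 0.802 to 75.6 CPM, and Flt1, a vascular growth factor receptor gene, rose by 1.06 on the log2 scale. Both adipocyte markers fell, and a list of 2 had no set test. The largest changes included the acetylcholine receptor gene Chrna1, which rose by 7.88 on the log2 scale, Ccn5 (0.0849 to 28.8 CPM) and the carboxylesterase gene Ces1g (0.0791 to 37.4 CPM). Both held 3 counts in the untreated parental libraries, and leaving out replicate 2 of these moved the fitted change of both by more than 1.5 times, as leaving out replicate 1 did for Ces1g. The largest falls included the lipid kinase gene Pik3c2g (-6.45).

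**Figure D2:**
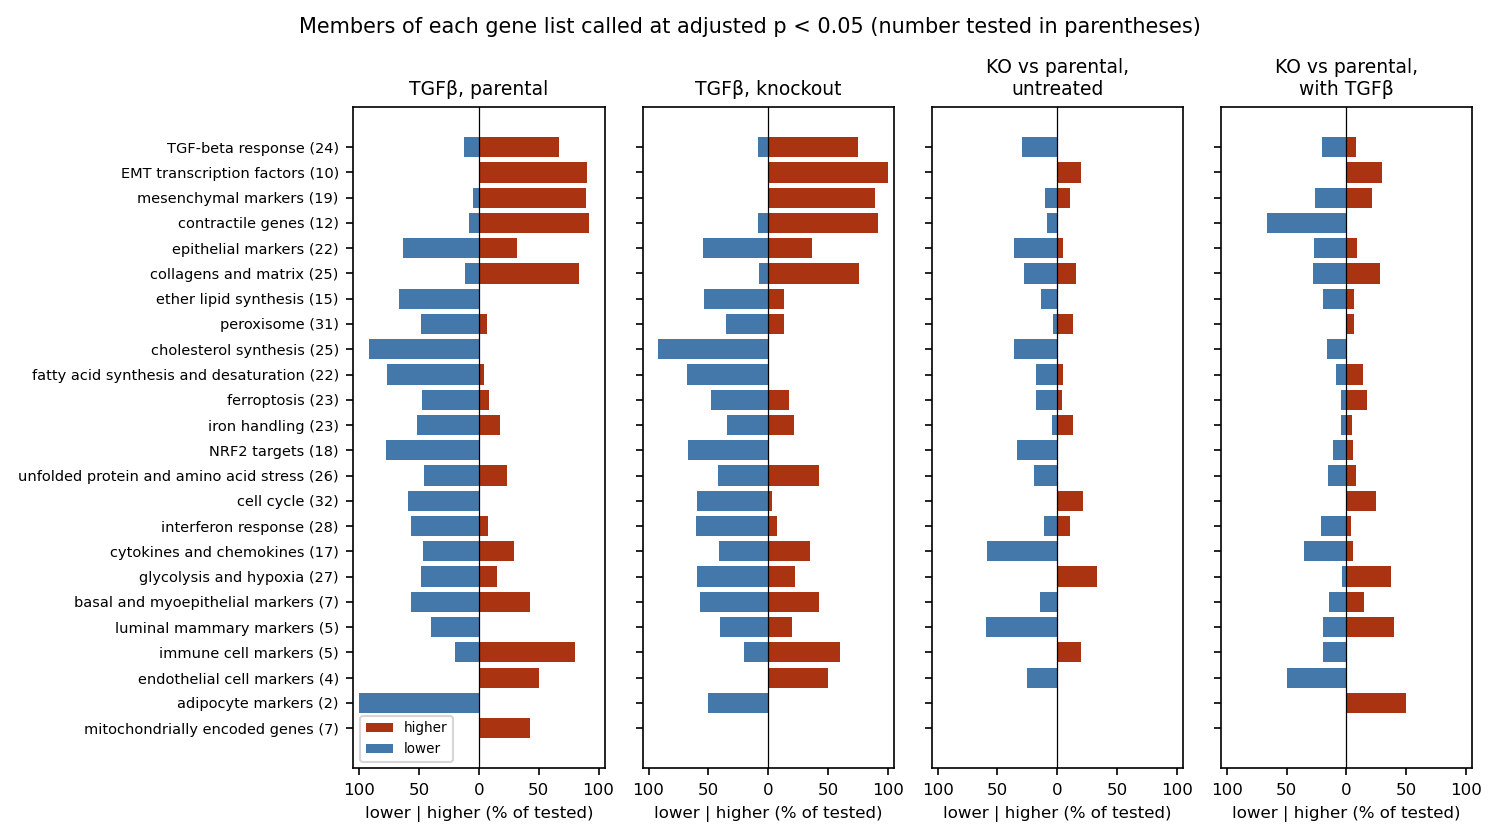
Percent of the measured members of each of 24 gene lists that were higher or lower at an adjusted p under 0.05, in 4 panels for TGF-β in parental cells, TGF-β in knockout cells, and knockout against parental cells without and with TGF-β. Cholesterol synthesis genes are lower in 23 of 25 cases with TGF-β in both lines, and contractile genes, 11 of 12 higher with TGF-β in both lines, are lower in 8 of 12 cases in knockout cells with TGF-β.

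The next comparison asked how knockout cells respond to TGF-β. With camera's preset correlation the lists of mesenchymal, matrix and contractile genes rose here too and those of sterol and fatty acid genes and NRF2 targets fell, and none passed with an estimated correlation. Fn1 rose by 3.83 on the log2 scale (standard error 0.12, adjusted p = 8.24e-10 in edgeR), to 7493 ± 89.1 CPM (SD, n = 2), and Vim by 1.09, to 2524 ± 101 CPM. Cdh1 fell by 2.53 (standard error 0.11, adjusted p = 1.18e-08), to 52.3 ± 0.0722 CPM. In knockout cells 6064 genes passed, with 3053 higher and 3011 lower, and 2645 changed by at least 1 on the log2 scale.

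Of the TGF-β response list 18 of 24 rose and 2 fell, or 20 and 2 adjusted over the list alone (camera adjusted p = 9.68e-08; adjusted p = 0.268 with an estimated correlation), Il11 by 7.93, Ltbp1 by 6.30 and Inhba by 3.06 on the log2 scale. All 10 transcription factors of the transition rose (camera adjusted p = 3.37e-07; adjusted p = 0.268 with an estimated correlation), with Zeb2 at 3.56, Hmga2 at 3.54, Runx1 at 2.02 and Zeb1 at 1.16. Mesenchymal markers rose in 17 of 19 cases and fell in 0 (camera adjusted p = 1.47e-10; adjusted p = 0.0971 with an estimated correlation), Pdgfrb by 7.71. Collagens and matrix genes rose in 19 and fell in 2 of 25 cases (camera adjusted p = 1.08e-09; adjusted p = 0.128 with an estimated correlation). Col6a3, Col1a1 and Col7a1 rose by 8.19, 7.50 and 7.36 on the log2 scale, and the bone and microglia gene Tmem119 by 8.82. Contractile genes rose in 11 and fell in 1 of 12 cases (camera adjusted p = 6.95e-06; adjusted p = 0.268 with an estimated correlation), with the actinin gene Actn1 at 1.84. Acta2 rose by 4.49, by 5.25 without replicate 2 of the untreated knockout cells and by 3.90 without replicate 1 of the treated knockout cells. Epithelial markers fell in 12 and rose in 8 of 22 cases (camera adjusted p = 0.193 and fry adjusted p = 0.0026, both toward lower). Their median log2 fold change was -0.54 and their mean 0.40, the mean resting on fitted values of genes such as Cldn4 that had almost no counts in untreated cells. Marveld2 fell by 3.60, while Cldn4 itself held 0 counts in the untreated and 354 counts in the treated knockout libraries.

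Sterol and fatty acid genes and NRF2 targets fell in knockout cells too. Cholesterol synthesis genes fell in 23 of 25 cases and rose in 0 (camera adjusted p = 3.37e-07; adjusted p = 0.468 with an estimated correlation), Hmgcs1 by 1.80, Insig1 by 1.42 and Sqle by 1.35 on the log2 scale. Fatty acid genes fell in 15 of 22 cases and rose in 0 (camera adjusted p = 2.18e-05; adjusted p = 0.468 with an estimated correlation), with Acss2 at -2.24 and the glycerolipid gene Gpam at -1.19. NRF2 targets fell in 12 of 18 cases and rose in 0 (camera adjusted p = 1.85e-04; adjusted p = 0.553 with an estimated correlation), Gsta4 by 3.89 and Gclc, the rate-limiting enzyme of glutathione synthesis, by 2.62. Cell cycle genes fell in 19 and rose in 1 of 32 cases, or 20 and 2 adjusted over the list alone (camera adjusted p = 6.44e-05; adjusted p = 0.374 with an estimated correlation), with Kif11 at -0.89 and the proliferation marker Mki67 at -0.68. Interferon response genes fell in 17 and rose in 2 of 28 cases (camera adjusted p = 7.88e-04; adjusted p = 0.234 with an estimated correlation), although Oasl2 rose by 3.75.

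Ether lipid genes fell in 8 and rose in 2 of 15 cases in knockout cells, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0409; adjusted p = 0.458 with an estimated correlation), Agmo, which cleaves ether lipids, with a log2 fold change of -6.34, Chpt1 of -1.98 and Pcyt2 of -0.90. That adjusted p was 0.0612 without replicate 2 of the treated knockout cells. Peroxisome genes fell in 11 and rose in 4 of 31 cases, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0334; adjusted p = 0.506 with an estimated correlation), with Cat at -2.05, Pxmp4 at -1.32 and Ech1 at -1.16, and the phytanoyl-CoA hydroxylase gene Phyh fell from 9.30 to 3.88 CPM. That adjusted p was 0.0736 without replicate 1 of the treated knockout cells, and 0.0897 in a fit without the genes of chromosomes 3 and 8 and of parts of 15 and X, which differ between the lines. Glycolysis and hypoxia genes fell in 16 and rose in 6 of 27 cases, or 18 and 6 adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.639 with an estimated correlation), and the adjusted p was 0.0852 without replicate 2 of the untreated knockout cells and 0.0916 with fry. Egln3 fell by 3.16, while Pfkfb4 rose by 2.33 and the hexokinase gene Hk2 by 1.53. Ferroptosis genes fell in 11 and rose in 4 of 23 cases, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0557 and fry adjusted p = 0.0228, both toward lower), with Acsl4 at -1.88 and Gss at -1.80. Iron genes fell in 8 and rose in 5 of 23 cases (camera adjusted p = 0.339), with Lcn2 at -5.01, Steap4 at 3.09, Cd44 at 1.76, the iron exporter gene Slc40a1 at -1.75, the transferrin receptor gene Tfrc at -0.75 and Fth1 at -0.57. Of 7 mitochondrially encoded genes 0 passed (camera adjusted p = 0.989).

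The responses of the lines to TGF-β resembled each other gene by gene. Across 14641 genes the log2 fold changes correlated at 0.887 (Pearson) and 0.787 (Spearman). This describes genes, which are not independent replicates, and the 2 responses share no library. Of 4617 genes called in both lines, 4583 (99.3%) moved in the same direction. Genes higher in both numbered 2257 where 650 were expected for independent calls, and genes lower in both numbered 2326 where 639 were expected.

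**Figure D3:**
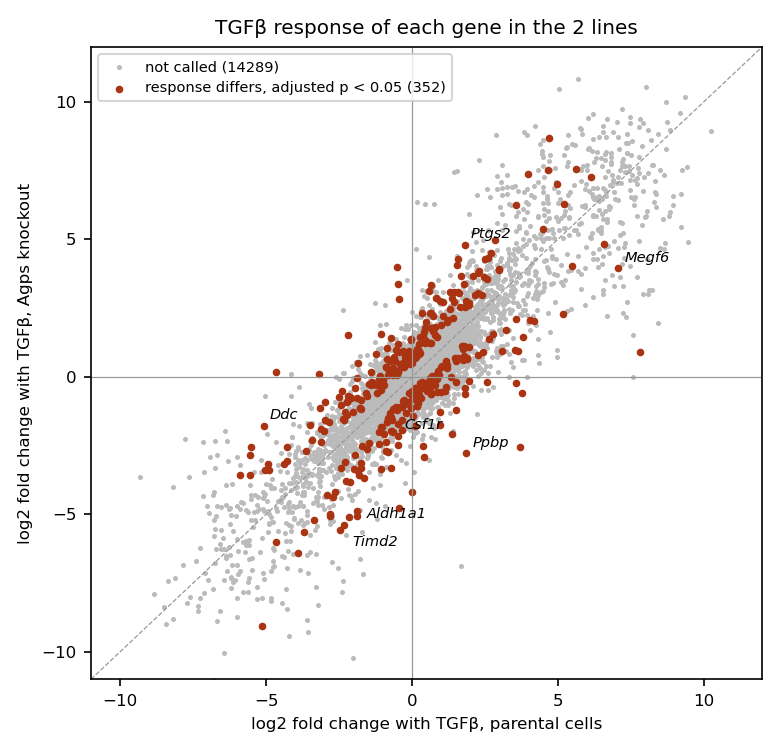
Log2 fold change with TGF-β of each of 14641 genes in parental cells (horizontal axis) and in knockout cells (vertical axis), with genes whose response differed between the lines (352 at an adjusted p under 0.05) in red and the rest in grey. Points gather along the diagonal (Pearson's r 0.887), with Aldh1a1 and Timd2 below it and Ddc above it.

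The third comparison asked what the knockout changed in untreated cells. With camera's preset correlation the lists of cytokine (10 of 17 called), sterol (9 of 25) and epithelial genes (8 of 22) were lower and that of glycolysis genes (9 of 27) higher than in untreated parental cells. None of them passed with an estimated correlation, and sterol and glycolysis genes did not pass fry. Xdh, which encodes xanthine dehydrogenase, went from 1.86 ± 0.845 CPM in parental to 9.43 ± 2.41 CPM in knockout cells (SD, n = 2), a log2 fold change of 2.36 (standard error 0.27, adjusted p = 1.92e-04 in edgeR). Sprr1b, an epidermal envelope gene (ENSMUSG00000048455, chromosome 3, 92436809 to 92438789), went from 82.8 ± 32.3 to 1.16 ± 0.202 CPM (log2 fold change -6.15, standard error 0.29, adjusted p = 6.19e-07). Cdh1 was lower by a log2 fold change of -1.09 (standard error 0.10, adjusted p = 5.92e-05). In all, 2000 genes passed, with 691 higher and 1309 lower, and 657 differed by at least 1 on the log2 scale. A fit on only the libraries compared called 1111 genes. The labels name 1 knockout line and no rescued line, so differences between the lines other than Agps cannot be separated from its loss.

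Many of the lower genes lay on a few chromosome segments, which were chosen after the values were seen. Among genes of an average log2 CPM of at least 3, the median log2 fold change of untreated knockout against parental cells was -0.30 on chromosome 3 (461 genes, 89.2% below 0). On chromosome 8 it was -0.38 below 90 Mb (325 genes, 95.7% below 0) and -0.84 above (196 genes, 98.0% below 0). It was -0.74 on X below 65 Mb (91 genes, 96.7% below 0) and -0.23 on chromosome 15 below 85 Mb (261 genes, 86.6% below 0), against 0.03 for all other genes. The 5 segments held 14.5% of the tested genes and 731 of the 1309 lower genes (55.8%), but 25 of the 691 higher genes. Outside them 578 genes were lower and 666 higher. A fit without the genes of the segments, added after this was seen, called 1050 genes in the untreated comparison, 571 lower and 479 higher, so the balance outside the segments depends on the fit.

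**Figure D4:**
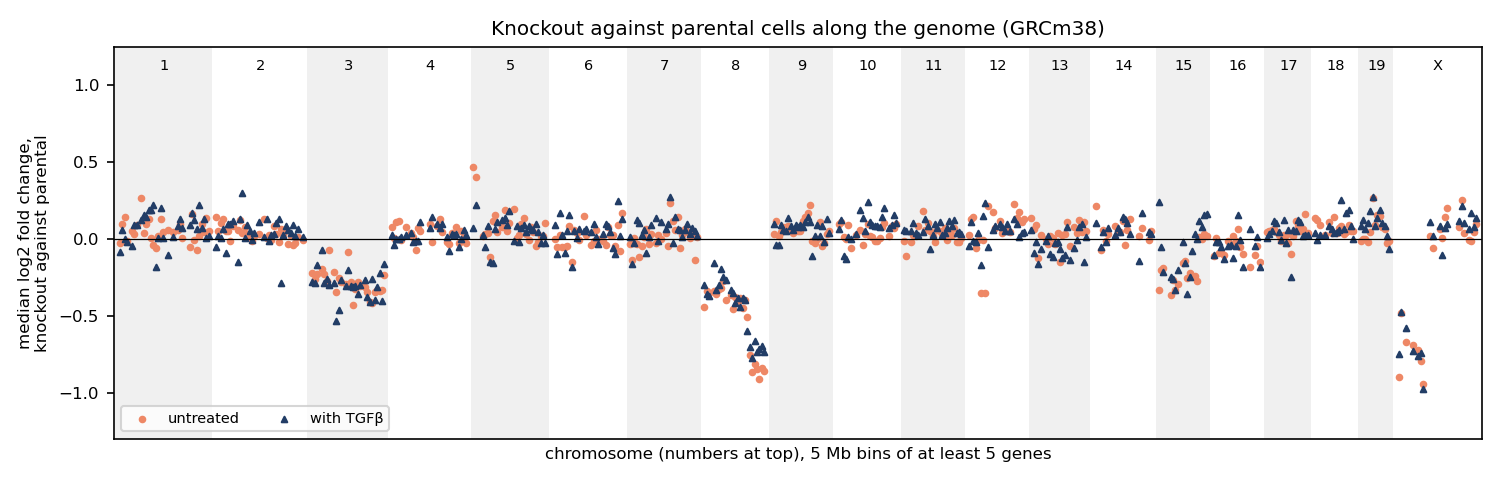
Median log2 fold change of knockout against parental cells in bins of 5 Mb with at least 5 genes, along the chromosomes, for untreated cells in orange and cells with TGF-β in blue. In untreated cells the bins of chromosome 8 above 90 Mb lie lowest together with those of X below 65 Mb, with medians over genes of -0.84 and -0.74.

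Genes on these segments include several of the largest differences. Vat1l on distal chromosome 8 went from 101.9 ± 8.83 CPM in untreated parental to 2.03 ± 0.746 CPM in untreated knockout cells (SD, n = 2; log2 fold change -5.64). On X, the interleukin receptor gene Il13ra1 went from 26.4 to 0.994 CPM (log2 fold change -4.72), and Fgf13 held 1110 counts in the untreated parental libraries and 1 in the untreated knockout libraries, and leaving out either of the latter moved its fitted change by more than 1.5 times. Cdh1, the splicing regulator gene Esrp2 (-0.89) and Gnpat (-0.66), which acts just before Agps in ether lipid synthesis, lie on distal chromosome 8. Besides Agps, Gnpat was the only ether lipid gene called among 15 measured (0 higher, 2 lower, camera adjusted p = 0.0613). Of 31 peroxisome genes 4 were higher and 1 lower (camera adjusted p = 0.834), with Phyh higher by 1.00 and Cat by 0.44 on the log2 scale.

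With camera's preset correlation the lists of cytokine, sterol and TGF-β response genes were lower in untreated knockout cells, and none passed with an estimated correlation. Of 17 cytokine and chemokine genes 10 were lower and 0 higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 2.18e-05; adjusted p = 0.183 with an estimated correlation). Tnfaip3, an NF-κB feedback gene, went from 124.4 ± 26.4 to 56.9 ± 15.2 CPM, a log2 fold change of -1.13. Ptgs2, which encodes cyclooxygenase-2, was at 405.9 ± 110 CPM in parental and 48.1 ± 31 CPM in knockout cells (log2 fold change -3.08, or -3.96 without replicate 2 of the untreated knockout cells). Of 24 TGF-β response genes 7 were lower and 0 higher, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00481; adjusted p = 0.468 with an estimated correlation). Ltbp1 was at -0.92, and Junb (-1.35) and Ccn1 (-0.94) lie on the segments of chromosomes 8 and 3. Cholesterol synthesis genes were lower in 9 of 25 cases and higher in 0, or 13 and 0 adjusted over the list alone (camera adjusted p = 2.36e-06; adjusted p = 0.468 with an estimated correlation and 0.0879 with fry). Mvd (-1.24), Msmo1 (-0.81), both of chromosome 8, and Ebp (-1.12) of X lie on the segments. Epithelial markers were lower in 8 and higher in 1 of 22 cases (camera adjusted p = 8.88e-04; adjusted p = 0.341 with an estimated correlation), among them Krt7 at -0.85. With the preset correlation the camera calls of the cytokine, TGF-β response, cholesterol and epithelial lists held in the fit without the genes of the segments.

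Glycolysis and cell cycle genes were higher in untreated knockout cells with camera's preset correlation, in calls that fry did not share. Of 27 glycolysis and hypoxia genes 9 were higher and 0 lower, or 12 and 1 adjusted over the list alone (camera adjusted p = 4.75e-06; adjusted p = 0.468 with an estimated correlation and 0.0916 with fry). P4ha2, a collagen prolyl hydroxylase gene, was higher by 1.31 on the log2 scale (standard error 0.10) and Pdk1, which restrains pyruvate oxidation, by 1.02. Pgam1, a glycolytic mutase gene that shares 36.2% of its 50-base sequences with other loci, was higher by 0.70. Of 32 cell cycle genes 7 were higher and 0 lower, or 8 and 0 adjusted over the list alone (camera adjusted p = 3.05e-04; adjusted p = 0.435 with an estimated correlation and 0.102 with fry), and the adjusted p was 0.0629 without replicate 2 of the untreated parental cells. The centromere gene Cenpf was higher by 0.59 and Kif11 by 0.39. Iron genes were higher in 3 and lower in 1 of 23 cases, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.319), with Steap4 at 1.31, Lcn2 at 0.84 and the heme oxygenase gene Hmox1, on chromosome 8, at -0.81.

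Lists of stress genes were lower in calls that single libraries decide. NRF2 targets were lower in 6 of 18 cases and higher in 0, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00713; adjusted p = 0.639 with an estimated correlation and 0.172 with fry). The adjusted p was 0.159 without replicate 2 of the untreated parental cells, 0.146 without replicate 1 of the untreated knockout cells and 0.148 in the fit without the segments. Osgin1, an NRF2 target of distal chromosome 8, was at -1.06. Unfolded protein and amino acid stress genes were lower in 5 of 26 cases and higher in 0 (camera adjusted p = 0.0143; adjusted p = 0.639 with an estimated correlation and 0.221 with fry), with Herpud1 of distal chromosome 8 at -1.07. Without replicate 2 of the untreated parental cells that adjusted p was 0.376, and without replicate 1 of the untreated knockout cells 0.171. Luminal markers were lower in 3 of 5 cases and higher in 0 (camera adjusted p = 0.0467; adjusted p = 0.506 with an estimated correlation and 0.0561 with fry), with Muc1 of chromosome 3 at -0.84. That adjusted p was 0.107 and 0.189 without the same 2 libraries, 0.0513 and 0.0502 without replicate 1 or 2 of the treated knockout cells, and 0.166 in the fit without the segments. Of the ferroptosis list, Chac1, which degrades glutathione, was at -1.44 and Dhodh, of pyrimidine synthesis and on distal chromosome 8, at -1.04, with 1 higher and 4 lower of 23 (camera adjusted p = 0.655). The other 14 lists with a set test had no camera call in this comparison, though fry passed ether lipid synthesis (adjusted p = 0.00485) and basal and myoepithelial markers (0.0135), both toward lower. The ether lipid list includes Agps itself, fry was not run without it, and the other called member, Gnpat, lies on a segment.

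The fourth comparison asked what the knockout changed in cells given TGF-β. With camera's preset correlation the lists of contractile and cytokine genes were lower and those of glycolysis and cell cycle genes higher in knockout than in parental cells. None of them passed with an estimated correlation, and glycolysis and cell cycle genes did not pass fry. Cnn1 was at 14.3 ± 0.128 CPM in treated parental and 4.63 ± 0.746 CPM in treated knockout cells (SD, n = 2), a log2 fold change of -1.62 (standard error 0.17, adjusted p = 1.08e-04 in edgeR). Has2, which encodes a hyaluronan synthase and lies on the chromosome 15 segment, was at 10.5 ± 0.239 CPM in parental and 127.9 ± 15.8 CPM in knockout cells (log2 fold change 3.60, standard error 0.17, adjusted p = 4.44e-07). Col6a3 reached 395.1 ± 79.4 CPM in knockout cells, with a log2 fold change of 2.98 (standard error 0.16). In all, 2618 genes passed, with 998 higher and 1620 lower, and 920 differed by at least 1 on the log2 scale. The count was 1188 and 1317 without replicate 1 or 2 of the treated parental cells, and 1588 and 1345 without replicate 1 or 2 of the treated knockout cells.

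The segments were lower here as well, with medians of -0.30 on chromosome 3, -0.35 and -0.69 on chromosome 8 below and above 90 Mb, -0.72 on X below 65 Mb and -0.08 on chromosome 15, against 0.06 for all other genes. They held 759 of the 1620 lower genes (46.9%) and 43 of the 998 higher genes, leaving 861 lower and 955 higher outside them. In the fit without them 1595 genes passed, 870 lower and 725 higher, the opposite balance. Maoa, a monoamine oxidase gene on X (ENSMUSG00000025037, 16619698 to 16687818), went from 41.9 ± 0.215 CPM in treated parental to 1.71 ± 0.3 CPM in treated knockout cells, a log2 fold change of -4.60. Cdh1 was lower by a log2 fold change of -1.35 and Cdh5 by -3.49, both on distal chromosome 8. Gnpat had one of -0.52 (adjusted p = 0.00315, or 0.0574 without replicate 1 of the treated parental cells). The knockout effects without and with TGF-β correlated at 0.510 (Pearson) and 0.436 (Spearman) across 14641 genes. Of 1069 genes called in both conditions 1025 (95.9%) had the same direction, 253 higher where 47.1 were expected for independent calls and 772 lower where 145 were expected.

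Contractile genes were lower in 8 of 12 cases and higher in 0, or 10 and 0 adjusted over the list alone (camera adjusted p = 2.83e-08; adjusted p = 0.234 with an estimated correlation), and none of the 12 lies on a segment. Acta2 was at 75.2 ± 1.86 CPM in treated parental and 7.55 ± 3.55 CPM in treated knockout cells, a log2 fold change of -3.31 that was -3.90 without replicate 1 of the treated knockout cells. Tpm1, which encodes a tropomyosin, went from 2996 ± 67.7 to 1445 ± 125 CPM (log2 fold change -1.05; a member of the list outside the rule for named genes, chosen after its values were seen). Tagln, which encodes transgelin and has 67.9% of its exonic length under genes on the opposite strand, was at -1.61. In untreated cells 1 contractile gene of 12 was lower in the knockout, 2 adjusted over the list alone, and 0 were higher (camera adjusted p = 0.44).

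**Figure D5:**
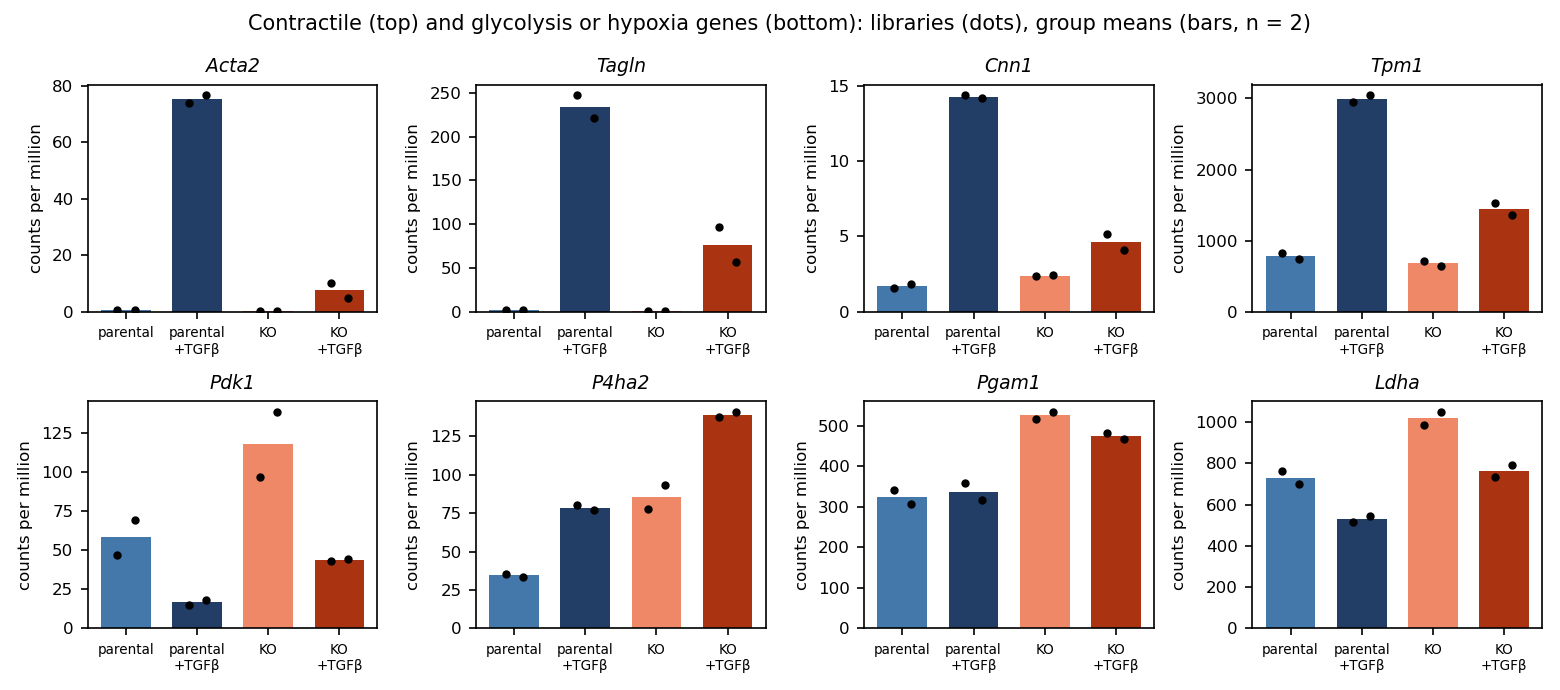
Levels (CPM) of 4 contractile genes (top) and 4 glycolysis or hypoxia genes (bottom), with dots for libraries and bars for the mean of each group (n = 2), by line and treatment. Tpm1 reaches 2996 CPM in treated parental but 1445 CPM in treated knockout cells, while Pdk1 is higher in knockout cells in both conditions.

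Glycolysis and hypoxia genes were higher in 10 and lower in 1 of 27 cases with TGF-β, or 13 and 1 adjusted over the list alone (camera adjusted p = 4.01e-05; adjusted p = 0.506 with an estimated correlation and 0.102 with fry). Pdk1 went from 16.6 ± 2.44 to 43.7 ± 0.746 CPM (log2 fold change 1.40) and P4ha2 was higher by 0.82. Cytokine and chemokine genes were lower in 6 and higher in 1 of 17 cases, or 9 and 1 adjusted over the list alone (camera adjusted p = 7.88e-04; adjusted p = 0.234 with an estimated correlation). Ccl20 had a log2 fold change of -2.30, the neutrophil attractant gene Cxcl1 of -1.76 and Tnfaip3 of -0.94. Cell cycle genes were higher in 8 of 32 cases and lower in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00336; adjusted p = 0.468 with an estimated correlation and 0.133 with fry), with Top2a higher by 0.54 and Aurka by 0.47. The other 19 lists with a set test had no camera call, though fry passed epithelial markers (adjusted p = 0.0185), ether lipid synthesis (0.0236) and endothelial markers (0.00699), all toward lower. The ether lipid list again includes Agps itself, and fry was not run without it. Among these 19 lists the lowest camera adjusted p was that of the mitochondrially encoded genes at 0.0654 with 0 of 7 called. Within those lists, the keratin genes Krt7 and Krt19 were lower at -1.50 and -1.24, Ocln was higher (1.32 CPM in parental and 3.74 CPM in knockout cells), Inhba was lower at -1.68 and the TGF-β receptor gene Tgfbr1 higher by 1.40. Hmga2 was higher by 1.37, Mboat2, which remodels phospholipids, by 0.95 and Steap4 by 2.81, and the basement membrane gene Col4a1 of chromosome 8 was lower at -0.85.

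The last comparison tested the difference itself, whether the change with TGF-β differed between the lines. The log2 change with TGF-β was larger in knockout cells for Tgfbr1, Ltbp1 and Fbln2 and smaller for the contractile gene Cnn1. Counts of untreated cells, summed per group, were lower in knockout than parental cells for Fbln2 (486 against 892) and Ltbp1 (182 against 295). With TGF-β they were 66370 against 61371 and 12801 against 10820. Aldh1a1, a retinal dehydrogenase gene (ENSMUSG00000053279, chromosome 19, 20492715 to 20643465), stood at 109.5 ± 15.7 and 109 ± 0.905 CPM in untreated parental and knockout cells and at 29.4 ± 1.44 and 3.24 ± 0.36 CPM with TGF-β (SD, n = 2). Its difference of log2 fold changes was -3.18 (standard error 0.19, adjusted p = 3.62e-05 in edgeR). Tgfbr1 went from 145.5 ± 2.83 to 193 ± 20.6 CPM in parental and from 165.1 ± 0.315 to 508.3 ± 34.2 CPM in knockout cells, a difference of 1.22 (standard error 0.13, adjusted p = 9.79e-04). In all, 352 genes passed, 183 with a more positive and 169 with a more negative response in the knockout (164 and 194 with upper quartile scaling). The count was 679 with a replicate block and 855 without a count filter. Without replicate 1 or 2 of the treated parental cells the count was 120 and 138, and without replicate 1 or 2 of the treated knockout cells 172 and 122.

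Of the 352 genes, 131 responded in both lines and more strongly in knockout cells, 79 responded in both and less strongly, and 28 responded in opposite directions. A further 60 were called with TGF-β in knockout cells and not in parental cells, and 54 the other way round. Ddc, which makes dopamine and serotonin from their precursors, fell by less in the knockout (difference 3.32), and Timd2, a ferritin receptor gene, fell by more (-3.05). Megf6 rose from 1.05 to 142.7 CPM in parental and from 2.00 to 31.0 CPM in knockout cells (difference -3.12). The chemokine gene Ppbp had a difference of -4.64, or -5.23 without replicate 1 of the treated knockout cells, and Ptgs2 one of 3.01, or 3.89 without replicate 2 of the untreated knockout cells. The differences were 1.08 for Ltbp1, 1.14 for the matrix gene Fbln2, 1.05 for Muc1, which lies on the chromosome 3 segment, and -1.67 for the macrophage receptor gene Csf1r, which has 15.1% of its exonic length under a gene on the opposite strand.

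Contractile genes had a more negative response in knockout cells in 3 of 12 cases and a more positive one in 0, or 5 and 0 adjusted over the list alone (camera adjusted p = 4.82e-06; adjusted p = 0.268 with an estimated correlation). Cnn1 showed the largest difference among them that passed, at -2.11 (standard error 0.29). The TGF-β response list moved the other way, with 3 of 24 genes more positive and 0 more negative (camera adjusted p = 0.00624; adjusted p = 0.468 with an estimated correlation and 0.13 with fry), and the adjusted p was 0.114 without replicate 1 of the untreated knockout cells. Of the ether lipid list 1 of 15 genes was more positive, 2 adjusted over the list alone, and of the peroxisome list 0 of 31 genes passed this test (camera adjusted p = 0.141 and 0.224).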

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

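The tests of gene dose, of a weaker general response, of the contractile genes against the segments, of immune cells, of fibroblasts and of single libraries behind the segments were chosen after the results they bear on had been seen. Differences between the lines in the response to TGF-β were picked out by the test of the difference itself, which 352 genes passed.

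Among genes with a more negative response in knockout cells the differences of log2 fold changes were -4.64 for Ppbp, -3.18 for Aldh1a1, -3.12 for Megf6, -3.05 for Timd2, -2.11 for Cnn1 and -1.67 for Csf1r. Among those with a more positive response they were 3.32 for Ddc, 3.01 for Ptgs2, 1.22 for Tgfbr1, 1.14 for Fbln2, 1.08 for Ltbp1 and 1.05 for Muc1. Without replicate 1 of the treated knockout cells Ppbp was at -5.23, and without replicate 2 of the untreated knockout cells Ptgs2 was at 3.89.

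Of the gene lists, 9 differed between the lines with camera's preset correlation. Contractile genes were more negative (adjusted p = 4.82e-06; adjusted p = 0.268 with an estimated correlation), as were mitochondrially encoded genes (0.0032; adjusted p = 0.545 with an estimated correlation, 0 of 7 called) and interferon response genes (0.0206; adjusted p = 0.374 with an estimated correlation, 0 of 28 called). More positive were the TGF-β response (0.00624; adjusted p = 0.468 with an estimated correlation), luminal markers (0.00766; adjusted p = 0.468 with an estimated correlation, 2 of 5 called) and cholesterol synthesis (0.00205; adjusted p = 0.605 with an estimated correlation, 0 of 25 called). So were NRF2 targets (0.00524; adjusted p = 0.639 with an estimated correlation, 0 of 18 called), stress genes (0.0308; adjusted p = 0.639 with an estimated correlation, 0 of 26 called) and fatty acid genes (0.0472; adjusted p = 0.639 with an estimated correlation, 1 of 22 called). Of these only the contractile list also passed fry (adjusted p = 0.0234), and fry passed immune markers (0.0366, toward more negative), which camera did not. Single libraries end most of these calls. Without replicate 2 of the untreated parental cells the adjusted p was 0.286 for cholesterol synthesis, 0.128 for NRF2 targets, 0.553 for stress genes, 0.399 for fatty acid genes and 0.0608 for mitochondrially encoded genes. Without replicate 1 of the untreated knockout cells it was 0.0715, 0.25, 0.279 and 0.264 for the first 4 of these and 0.114 for the TGF-β response. Without replicate 2 of the treated knockout cells it was 0.0665 for NRF2 targets, 0.284 for stress genes, 0.152 for fatty acid genes and 0.144 for mitochondrially encoded genes, and without replicate 1 of the treated parental cells 0.0788 for fatty acid genes. In the fit without the segments it was 0.123 for luminal markers, 0.0854 for stress genes and 0.108 for fatty acid genes.

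Genes of 5 chromosome segments were lower in knockout cells in both conditions. GC content and gene length do not account for it: in 9 strata of both, the median log2 fold change of the segments minus that of other genes was -0.46 to -0.34 over both conditions. No single library carried it, since the lowest parental library lay above the highest knockout library by 0.34 (medians of 0.18 and -0.16). A candidate explanation is a difference in gene dose between the lines, because segments set in untreated cells were lower with TGF-β in 88.7% to 99.5% of their genes on chromosomes 3, 8 and X. For chromosome 15, where 63.6% of genes were lower with TGF-β, this stays open. Any lasting difference between the lines would persist with TGF-β too. A ratio of the lines cannot tell a lower dose in knockout cells from a higher one in parental cells. DNA was not analysed here, and with 1 knockout line a difference in dose cannot be separated from an effect of Agps.

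As a list, contractile genes had a more negative response to TGF-β in knockout cells, with a median difference of -0.45, 10 of 12 below 0 and 3 of 12 called (adjusted p = 0.268 with an estimated correlation). A weaker response to TGF-β in general is argued against by the TGF-β response list, whose median was 0.36: the contractile median lay -0.81 from it (bootstrap 95% interval -1.92 to -0.32 over 10000 draws of genes). Genes of a list are not independent, and the interval leaves out the spread between libraries. The TGF-β response list was itself lower in untreated knockout cells with camera's preset correlation, and had no camera call between the treated lines. Its median of 0.36 thus goes with a lower untreated level, and fry did not share its call. It argues only against a smaller log2 change of that list. Leaving out each library gave contractile medians of -0.51 to -0.39, so 1 library does not carry the more negative response. Gene dose of the segments stays open, since 0 of the 12 lie on them, and so the median of -0.45 in the fit without their genes decides nothing about the dose of a regulator there. With 1 knockout line this cannot be told apart from an effect of Agps.

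Some genes known from other cell types rose with TGF-β in both lines, among them Cdh5 (up to 75.6 CPM) and Col1a1 (up to 137 CPM). As lists, immune and endothelial markers had no camera call though fry passed both (camera adjusted p = 0.0851 and 0.0645 in parental, 0.251 and 0.311 in knockout cells), and Csf1r fell in both lines. Immune cells in the cultures are argued against by 8 abundant immune transcripts, whose highest levels with TGF-β had a median of 0.149 CPM (0 to 2.33). Tyrobp, C1qa, C1qb and C1qc held 0 counts with and without TGF-β. The highest, Cd74, stood at up to 2.09 CPM without TGF-β. Its counts, summed per group, rose from 20 to 72 in parental cells and went from 83 to 80 in knockout cells. Fcer1g, another of the 8, rose as well, from 9 to 102 counts over both lines (up to 1.97 CPM). Endothelial cells are argued against by 7 endothelial transcripts with a median of 0.053 CPM (0 to 0.953). Fibroblasts are argued against by Col1a2, Col3a1, Dcn and Lum, whose ratios to Col1a1 had a median of 0.00859 (0 to 0.0204). Expression of these genes by the PyMT-1099 cells themselves may be the source, which no sort or single-cell measurement here tests.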

How the results depend on the processing

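The fit without the chromosome segments was chosen after the data were seen. No called list and no named gene reversed its direction in any alternative run. All 180 named gene results kept their direction and call with RLE and upper quartile scaling, without the count filter, with a minimum count of 50, with DESeq2, with limma-voom and with the replicate block, as did the 168 fitted on only the libraries compared. With 1 library left out 1439 of these results held and 1 lost its call. In such fits the lone library of a group is assumed to vary like the other groups.

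Requiring a log2 fold change of at least 1 left 2688 genes for TGF-β in parental cells, 2645 in knockout cells, 657 for the knockout untreated, 920 with TGF-β and 204 for the difference of responses. On only the libraries compared the untreated knockout effect had 1111 genes and that with TGF-β 3596. The fit reported shares its estimate of the spread over all groups. Spread between libraries was unequal, with a median absolute log2 difference of 0.180 and 0.174 in untreated parental and knockout cells. With TGF-β it was 0.116 and 0.157. Whether this accounts for the counts of 1111 and 3596 was not tested. Upper quartile scaling split the genes into 3448 higher and 2829 lower for TGF-β in parental cells, 848 and 1190 for the knockout untreated and 164 and 194 for the difference of responses. It moved the log2 fold changes by medians of 0.0421, 0.0352 and -0.0297 in these contrasts, the direction in which the splits moved. The medians were 0.0124 for TGF-β in knockout cells and 0.0055 for the knockout effect with TGF-β. The difference of responses had 855 genes without a count filter, and the cause was not tested. With a replicate block it had 679 genes. The labels do not say that libraries of 1 number share a day or culture, and the deviations of replicate 1 correlated at 0.0218 to 0.308 between groups. Without the segments, and so with fewer genes tested, the knockout effect had 1050 genes untreated and 1595 with TGF-β. Leaving out 1 library gave 1188 to 2922 genes for the knockout effect with TGF-β and 120 to 421 for the difference. The correlation of TGF-β responses was 0.9345 among genes of an average log2 CPM of at least 3 and 0.8338 to 0.8621 with 1 library out. That of the knockout effects was 0.6335 and 0.4008 to 0.4575. Of 115 list tests 49 passed, and 0 with an estimated correlation, where 17 had an unadjusted p under 0.05 and fry passed 50. The calls that fry did not share were glycolysis and hypoxia (TGF-β in knockout cells and both knockout effects), the cell cycle (both knockout effects), cholesterol synthesis, NRF2 targets, stress genes and luminal markers (knockout untreated), and each list of the difference but the contractile one. Depth of 17007268 to 21311831 counts limits genes near the count minimum.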

Other observations

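Several of the largest changes lay outside the gene lists, and the genes given here were picked from those the naming rule allows after their values were seen. Ugt2b36, which conjugates glucuronic acid, stood at 32.3 ± 4.68 CPM in untreated and 0.053 ± 0.00344 CPM in treated knockout cells (SD, n = 2), and at 47.5 and 1.33 CPM in parental cells. Cyp2c65, a cytochrome P450 gene that shares 20.6% of its 50-base sequences with other loci, went from 55.5 to 0.265 CPM with TGF-β in knockout cells. The acute phase gene Orm1, with 20.4% shared sequence, was higher in untreated knockout than parental cells by 3.24 on the log2 scale (20.8 against 2.20 CPM), and A1cf, an RNA editing cofactor gene, by 2.80 (28.8 against 4.15 CPM).

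Sgsm1 was higher by 2.61 on the log2 scale in untreated cells and by 3.66 with TGF-β. With TGF-β the collagenase gene Mmp13 was higher by 2.96 (18.9 against 2.43 CPM) and the glutathione transferase gene Gsto2 by 2.96 (24.4 against 3.12 CPM).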
